A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

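Seedlings grew for 5 days with 14 h of light at 28 °C and 10 h of darkness at 24 °C, and their apices were dissected under a microscope, per the labels' protocols. RNA libraries were made with the Illumina TruSeq kit. Trimmomatic, TopHat and Cufflinks are named for them in the submitters' processing notes, with versions not given in the sources used here. Each expression table deposited by the authors gives FPKM per locus with a lower and an upper confidence bound, per the file headers. The genome build and annotation are not given in the sources used here, and locus names are of the LOC_Os kind. For ChIP-seq, chromatin of 200 to 500 bp was precipitated with anti-FLAG, and Trimmomatic 0.32, Bowtie2 2.1.0 and SAMtools 0.1.17 are named in the submitters' processing notes. Peaks were called with MACS 1.4.2 at a p-value cutoff of 1e-05, 1 list per library against its own control, per the file headers. The deposited peak lists give for each peak a tag count, a score that is 10 times the negative log10 of the p-value, a fold enrichment over input, which is a ratio, and a false discovery rate in percent, per the file headers. These are the authors' values, used here to describe and rank peaks within a list. The tags before removal of duplicates numbered 5043282 and 7509947 per the file headers. A sample of input DNA in the labels has no file that was analysed here.

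The 6 tables share 57567 loci. Of these, 1848 have no gene name and hold 71.2 to 95.3% of the summed FPKM, the 4 highest being 33 to 41 bp long. They were left out of the tests, with 13 loci that have a failed estimate in some library. 1100 loci join several genes, and 6761 of 55719 named loci share coordinates with another, so that their reads may be divided. Named loci sum to between 700781 and 821366 FPKM per library, and median ratios to the geometric mean are 0.997 to 1.01. Total depth is unknown. Low values (below 0.15 FPKM) were searched for steps of 1 read. Of their ratios to wild-type replicate 1, 75.0 to 77.3% lay within 0.05 log2 of a ratio of 1 to 4 reads. The estimate from them was 0.973 to 1.04 times as many reads per FPKM as in that library. It used only ratios close to equality, so it could not come out far from equality and leaves relative depth unsettled. Pearson correlations of log2(FPKM + 1) between libraries were 0.962 to 0.987, and no 2 tables were alike. Within a genotype they were 0.980 to 0.987, and wox11 replicate 1 with jmj705 replicate 1 had 0.981. Wild-type replicate 1 had 0.962 to 0.972 with the mutant libraries, and wild-type replicate 2 had 0.973 to 0.980.

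Loci with at least 1 FPKM in at least 2 of the 6 libraries (21480) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per genotype, 3 residual degrees of freedom, a mean-variance trend in the empirical Bayes step (4.25 prior degrees of freedom) and Benjamini-Hochberg adjustment per contrast at 0.05. The contrasts were wox11 and jmj705 against wild type and jmj705 against wox11. The 2 libraries of a genotype are called biological repeats in the series' design text, and p-values measure the spread between these samples. In data simulated for 21480 loci with 200 changed, the test called 77.7% of 2-fold and 99.7% of 4-fold changes for wox11, and 76.5% and 98.9% for jmj705, with 8.13% and 7.88% of calls false.

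Gene lists were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 21 lists held 258 genes: the mutated genes; light harvesting and photosystems; Calvin cycle; chlorophyll synthesis; chloroplast biogenesis; circadian clock; meristem; YABBY and leaf polarity; floral MADS-box; Polycomb and demethylases; auxin; cytokinin; gibberellin; cell division; secondary wall and vascular; root; seed; heat shock; hypoxia; jasmonate and defence; and diterpenoid phytoalexins. Symbols were looked up in the RefSeq table of assembly ASM3414082v1, another build, of which no coordinate is printed. 167 lay at a like place, 85 symbols were not found there and rest on the written lists, and 6 that lay elsewhere were left out, with 6 on merged and 2 on several loci, leaving 244. The files pair no descriptions with loci, so 6 further lists defined by keywords were not run. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists with at least 2 tested genes. In simulated data with the Calvin cycle list alone shifted, camera at the preset correlation called it and also 2 of 17 unshifted lists. With an estimated correlation no list passed in any contrast. By fry, which tests whether members move one way without comparing them with other genes, the Calvin cycle (adjusted p = 0.0368 and 0.0105) and chlorophyll synthesis (adjusted p = 0.018 and 0.0135) passed in wox11 and jmj705, down in both.

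Genes named are WOX11 and JMJ705; per mutant, up to 6 largest rises and falls among called genes with a name, at least 5 FPKM in the higher genotype and libraries outside the wild-type range; up to 3 genes of smallest p from each list with a call; up to 5 named genes called alike in both mutants; and listed genes with a peak. RBCS3, RBCS4, SBP, cpFBA, GAPB, PRK, FNR1, PRR1, ELF3, RCc3, IAA13, IAA9, IAA31, GLK1, PDC2, MADS58, the phytoalexin genes and 2 locus IDs without a symbol were chosen after their values were seen. Shared wild-type libraries were allowed for with 100 simulations of unchanged groups. Peaks were compared by overlap of at least 1 bp with 1000 random placements within chromosomes, and in 1000 simulated peaks the overlap step found 400 of 400 planted overlaps and 4 among the others. Genes near peaks are loci within 1 kb on either side, since the files give no strand, where the plan had 1 kb upstream. They were tested with camera, fry and Fisher's exact test. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, quantile and median-ratio scaling, a replicate block, fits of 2 genotypes, a 2-fold minimum, each library left out, other peak overlaps and windows, the better-scoring part of each list, and expression-matched backgrounds. Inclusion of unnamed loci, a fit without the trend and removal of merged loci were added after seeing the data. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.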

Results

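Messenger RNA was measured in the shoot apex, the 2 to 3 mm tip of the shoot that holds the meristem and the youngest leaves, of 5-day-old rice seedlings of the cultivar Hwayoung. Seedlings were wild type, wox11 mutant or jmj705 mutant, with 2 libraries per genotype that the series' design text calls biological repeats. WOX11 is a homeobox transcription factor of the WUSCHEL family, and JMJ705 is an enzyme that removes methyl groups from lysine 27 of histone H3. JMJ705 on chromatin was mapped by anti-FLAG chromatin immunoprecipitation and sequencing (ChIP-seq) in apices that over-express JMJ705 in a wild-type or in a wox11 background, with 1 peak list each. The expression values are FPKM, fragment numbers scaled by transcript length and library size, so total read counts per library are unknown. What 1 read was worth, estimated from low values, came to 0.958 to 1.03 times its value in wild-type replicate 1. That estimate used only ratios close to equality, so it does not settle whether the 6 libraries were alike in depth. Levels are given as mean ± SD with n = 2 per genotype, fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p stands for limma's moderated test with Benjamini-Hochberg adjustment over 21480 loci. The build of the coordinates is not given in the sources used here.

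The 2 mutated genes were looked at first, since they check the labels. WOX11 (LOC_Os07g48560, chromosome 7, 29073043 to 29075687) stood at 4.76 ± 0.342 FPKM in wild type, 1.30 ± 0.272 in wox11 and 6.06 ± 2.11 in the libraries labelled jmj705. Its level in the wox11 libraries lay below both wild-type libraries, at log2 change -1.33 (-1.81 and -0.63 with pseudocounts of 0.1 and 5 FPKM). WOX11 had an SE of 0.23 and adjusted p = 0.0575 there, which misses the threshold of 0.05. It passed with a pseudocount of 0.1 (adjusted p = 0.0461), in a fit of 2 genotypes (0.0417) and without jmj705 replicate 1 (0.0314) or 2 (0.0331), in a range of 0.0314 to 0.295 over its alternatives. JMJ705 (LOC_Os01g67970, chromosome 1, 39493115 to 39500079) stood at 7.07 ± 0.482 FPKM in wild type, 8.25 ± 0.202 in wox11 and 13.1 ± 0.840 in the libraries labelled jmj705, above both wild-type libraries in each (log2 change 0.81, SE 0.13, adjusted p = 0.0634). JMJ705 therefore went against the label in size, without passing the test. Neither the lesion in jmj705 nor the part of the transcript that was counted is given, so a transcript that is made but changed would not be seen. Every direction given for jmj705 rests on that label. Directions of wox11 against wild type rest on the wild-type label, since an exchange of wild-type and jmj705 labels could not be decided.

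**Figure D1:**
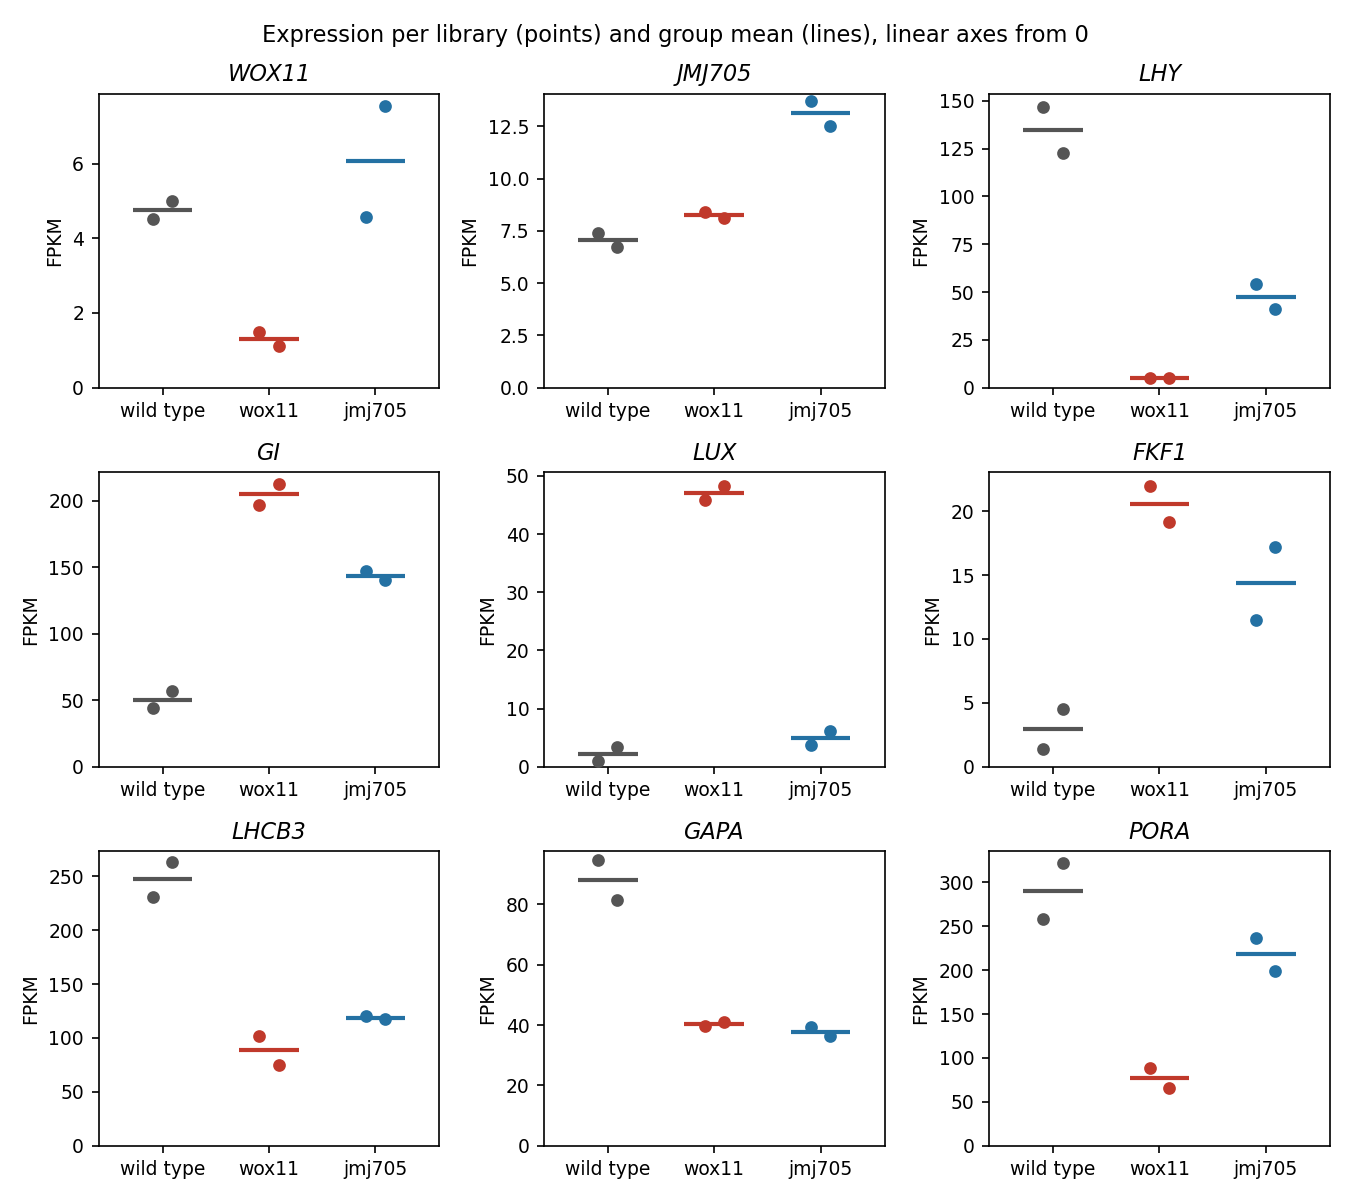
FPKM (linear axis from 0) of 9 genes in the 3 genotypes, with points for single libraries and lines for means of 2 libraries. LHY lies at 135 FPKM in wild type, 5.08 in wox11 and 47.5 in the libraries labelled jmj705, and JMJ705 is highest in the libraries labelled jmj705.

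The first comparison, wox11 against wild type, asks which genes depend on WOX11 in the apex. The wox11 apices held far less transcript of the morning clock gene LHY, more of the evening clock genes GI, LUX and FKF1, and less of several photosynthesis genes. LHY (LOC_Os08g06110), a MYB transcription factor at the core of the clock, fell from 135 ± 17 to 5.08 ± 0.325 FPKM (log2 change -4.48, SE 0.16, adjusted p = 6.23e-05). GI, the rice GIGANTEA, rose from 50.2 ± 8.95 to 205 ± 11.1 FPKM (log2 change 2.02, SE 0.15, adjusted p = 0.00265). LUX, a component of the evening complex, rose from 2.18 ± 1.79 to 47.1 ± 1.64 FPKM (log2 change 4.04, SE 0.37, adjusted p = 0.00627), and FKF1, a blue-light receptor, from 2.94 ± 2.18 to 20.6 ± 2.02 FPKM (log2 change 2.57, SE 0.37, adjusted p = 0.0318). Of the 10 clock genes, 3 rose, 1 fell and 6 did not pass. Adjusted over the list alone, 4 rose and 1 fell, the fourth riser being PRR1, at 18.4 ± 6.90 FPKM in wild type and 42.8 ± 2.01 in wox11. As a set the clock list leaned up (median 0.25, camera adjusted p = 0.00489), a call that was lost at adjusted p = 0.377 with an estimated correlation. The median was 0.10 and 0.63 without wild-type replicate 1 or 2, and 0.10 and 0.47 without wox11 replicate 1 or 2. LHY kept its call under each alternative (adjusted p 2.05e-05 to 0.00503). The call of LUX ended without wox11 replicate 1 (adjusted p = 0.0584) or 2 (0.0662), that of FKF1 likewise (0.201 and 0.156) and that of GI without wox11 replicate 2 (0.0503). With no FPKM filter LUX had 0.111 and FKF1 0.212, and FKF1 had 0.0531 with quantile normalization and 0.058 in a fit of 2 genotypes. Over all alternatives the adjusted p ran from 0.00118 to 0.111 for LUX, 0.00529 to 0.212 for FKF1 and 0.00182 to 0.0503 for GI.

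Photosynthesis genes made up most other calls among listed genes in wox11. Genes of the antenna proteins fell, LHCB3 from 247 ± 23.1 to 88.4 ± 18.8 FPKM (adjusted p = 0.0142), LHCB5 from 189 ± 8.19 to 72.7 ± 24.8 (adjusted p = 0.0419) and LHCA3 from 87.6 ± 6.17 to 26.1 ± 9.84 (adjusted p = 0.0318). Of the 26 light harvesting and photosystem genes, 3 fell and 23 did not pass over all genes, while 24 fell and 1 rose adjusted over the list alone. The riser was FNR1, a ferredoxin reductase gene, at 11.9 ± 0.383 FPKM in wild type and 18.2 ± 1.35 in wox11. The list median was -1.03 (camera adjusted p = 1.07e-21; adjusted p = 0.377 with an estimated correlation). In the Calvin cycle list, 3 of 13 genes fell. These were RCA, which encodes Rubisco activase (26.5 ± 2.09 to 11 ± 0.616 FPKM, adjusted p = 0.00852), GAPA, a chloroplast glyceraldehyde-phosphate dehydrogenase gene (88.1 ± 9.34 to 40.3 ± 1.00, adjusted p = 0.0122), and RBCS2, a small-subunit gene of Rubisco (41.6 ± 2.52 to 22.9 ± 2.05, adjusted p = 0.0319). Its relatives RBCS3 and RBCS4 had log2 changes of 0.03 and 0.06, and reads of such close relatives can be split between them by the counting. Adjusted over the list alone, 5 Calvin cycle genes fell, and the list fell by camera (median -0.08, mean -0.35, adjusted p = 0.0035; adjusted p = 0.354 with an estimated correlation). Its median was -0.042 and -0.14 without wild-type replicate 1 or 2 and -0.032 with quantile normalization. Chlorophyll synthesis genes fell as a list too (median -0.49, camera adjusted p = 7.34e-07; adjusted p = 0.192 with an estimated correlation), with 2 of 14 past the test and 8 adjusted over the list alone. PORA, a light-dependent protochlorophyllide reductase gene, fell from 290.3 ± 45.3 to 77.2 ± 16.4 FPKM (adjusted p = 0.00987) and GUN4, a regulator of magnesium chelatase, from 34.2 ± 2.25 to 18.1 ± 0.0962 (adjusted p = 0.0225). HEMB stood at 51.9 ± 4.51 and 31.4 ± 0.626 FPKM (adjusted p = 0.0719). Each of these 8 calls ended without wox11 replicate 2 (adjusted p 0.0909 to 0.226) and with no FPKM filter (0.0575 to 0.214). Those of LHCA3, LHCB3, LHCB5, RBCS2 and GUN4 ended without either wild-type library (0.0553 to 0.188), those of RCA and GAPA without wild-type replicate 1 (0.0604 and 0.0721), those of RCA, GAPA, RBCS2 and GUN4 without wox11 replicate 1 (0.0721 to 0.177), and those of LHCB5 and RBCS2 without either jmj705 library (0.0501 to 0.0704). LHCA3, LHCB5 and RBCS2 also lost the call in a fit of 2 genotypes (0.058 to 0.0828), LHCA3 and LHCB5 with quantile normalization (0.0535 and 0.0913), LHCB5 with median-ratio scaling (0.0541), and LHCB5 and RBCS2 without the trend (0.0581 and 0.0557). Over all alternatives the adjusted p of these 8 genes ran from 0.00454 to 0.226. The loci of LHCB3, RCA, GUN4 and FNR1, like those of cpSRP43, HSP101, BC1 and IAA13, share their coordinates with another locus in the files, so their reads can be divided between entries.

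Among the other lists, meristem genes leaned down in wox11 with a median of -0.38 (camera adjusted p = 0.0035; adjusted p = 0.354 with an estimated correlation), although 0 of 10 passed limma's test singly and 3 were lower at an unadjusted p under 0.05. At an FPKM filter of 5 its adjusted p was 0.0601, in a range of 3.40e-04 to 0.0601, and with a pseudocount of 5 its median was -0.19. The KNOX gene OSH71 stood at 50.9 ± 1.30 FPKM in wild type and 34 ± 0.525 in wox11 (adjusted p = 0.195), WOX4 at 2.92 ± 0.226 and 1.71 ± 0.240 (adjusted p = 0.329), and PLA1, which sets the pace of leaf initiation, at 15.5 ± 2.90 and 10.7 ± 1.41 (adjusted p = 0.451). Secondary wall and vascular markers leaned up (median 0.19, camera adjusted p = 0.0314; adjusted p = 0.377 with an estimated correlation), with CESA4 at 17 ± 0.496 and 22.2 ± 1.88 FPKM, BC1 at 1.43 ± 0.137 and 2.37 ± 0.00566, and CESA9 at 9.04 ± 1.16 and 10.4 ± 0.315. Of its 5 genes 0 passed and 2 were higher at an unadjusted p under 0.05. The list's adjusted p was 0.241 without wild-type replicate 2, 0.0741 without wox11 replicate 2, 0.0601 at a filter of 5 FPKM and 0.0541 with quantile normalization, in a range of 0.0187 to 0.241. Its median was 0.32 and 0.069 without wild-type replicate 1 or 2. Heat shock genes leaned down (median -0.91, camera adjusted p = 0.00489; adjusted p = 0.53 with an estimated correlation), with 0 of 7 past the test and 3 lower at an unadjusted p under 0.05. In wild-type replicate 1 HSP101 stood at 11.9 FPKM against 1.91 in replicate 2, HSP17.9 at 46.0 against 11.7 and HSP17.4 at 7.55 against 3.13, and without that library the list's adjusted p was 0.253. It was 0.204 without wox11 replicate 2 and 0.102 at a filter of 5 FPKM, in a range of 8.94e-08 to 0.253. The median was -0.14 and -1.68 without wild-type replicate 1 or 2, -1.44 and -0.29 without wox11 replicate 1 or 2, and -1.51 and -0.46 with pseudocounts of 0.1 and 5. HSP101 passed without wild-type replicate 2 (adjusted p = 0.00864, range 0.00864 to 0.903). Jasmonate and defence genes leaned up (median 0.49, camera adjusted p = 0.0428; adjusted p = 0.597 with an estimated correlation). Their 3 members of smallest p were PR1a at 0.561 ± 0.406 and 2.20 ± 0.623 FPKM, WRKY45 at 1.84 ± 1.03 and 5.89 ± 2.66, and WRKY53 at 12.4 ± 11.1 and 21.6 ± 6.26. Of 12 genes 0 passed over all genes, 1 was higher at an unadjusted p under 0.05, and 1, PR1a, rose adjusted over the list alone. Without wild-type replicate 1 the list median was -0.13 (adjusted p = 0.53), and without wox11 replicate 1 it was 0.20 (adjusted p = 0.208). The call also ended with a pseudocount of 5 (adjusted p = 0.0918), a filter of 5 FPKM (0.0601), quantile normalization (0.0609) and median-ratio scaling (0.0628), in a range of 8.02e-04 to 0.53. The median was 1.42 without wild-type replicate 2, 0.75 without wox11 replicate 2, 0.78 and 0.24 with pseudocounts of 0.1 and 5, and 0.30 with no FPKM filter.

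Lists that did not pass in wox11 were auxin (median -0.23, camera adjusted p = 0.0714), root markers (median -0.28, 0.0826), YABBY and leaf polarity (median -0.16, 0.157), floral MADS-box genes (median -0.26, 0.157) and hypoxia genes (median -0.24, 0.202). Polycomb and demethylase genes (median 0.06, 0.351), gibberellin genes (median -0.05, 0.639), cytokinin genes with type-A response regulators (median 0.05, 0.639) and cell division genes (median -0.04, 0.808) did not pass either. Chloroplast biogenesis genes had a median of 0.07 and a mean of -0.13, and the test leaned down (camera adjusted p = 0.462). Adjusted over the list alone, 3 of these fell (cpSRP43, GLK1 and SIG1), as did 1 auxin gene (IAA31), 1 root marker (RCc3) and 1 hypoxia gene (PDC2), against 0 of each list over all genes. At an unadjusted p under 0.05, 3 chloroplast biogenesis, 2 root, 1 hypoxia and 2 YABBY genes were lower, and 2 auxin genes were higher and 2 lower. The auxin list passed with no FPKM filter (adjusted p = 0.0188), at a filter of 5 (0.0184) and without wild-type replicate 2 (0.0489) or wox11 replicate 1 (0.0106), in a range of 0.0106 to 0.438. Root markers passed without wild-type replicate 2 (0.0112) or wox11 replicate 1 (0.00185), in a range of 0.00185 to 0.53, and the YABBY list without wox11 replicate 2 (0.0258), in a range of 0.0258 to 0.648. Without wild-type replicate 1 the auxin median was -0.089 and the root median -0.034. The root median was -0.51 and 7.4e-04 without wox11 replicate 1 or 2. The root marker RCc3 stood at 118 ± 39.7 FPKM in wild type and 42.9 ± 26.8 in wox11 (adjusted p = 0.222). RR2, a type-A response regulator, stood at 19.4 ± 2.87 and 23.0 ± 1.88 FPKM (adjusted p = 0.684). All 7 seed and aleurone markers stayed below 1 FPKM in each of the 6 libraries, and 11 of the 15 floral MADS-box genes stayed below the FPKM filter.

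Over all tested loci, 180 passed in wox11, 98 higher and 82 lower, most of them outside the gene lists and so without a name here. That count fell to 67 and 89 without wild-type replicate 1 or 2, to 34 and 21 without wox11 replicate 1 or 2, and to 34 with no FPKM filter. 

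**Figure D2:**
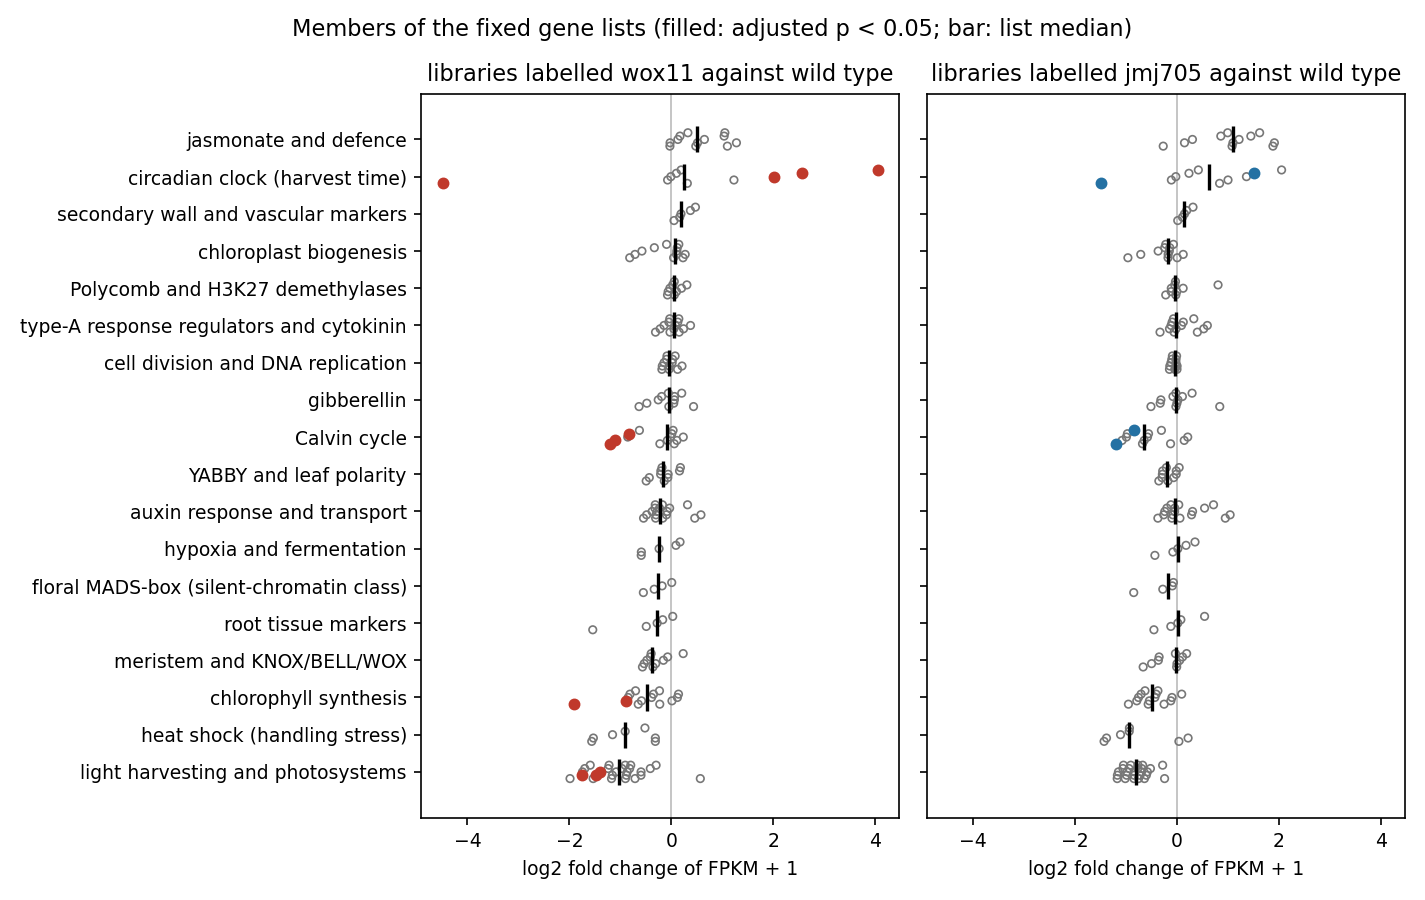
Log2 fold change (FPKM + 1) of each tested member of 18 gene lists, in wox11 (left) and in the libraries labelled jmj705 (right), both against wild type, with circles for genes, filled at adjusted p under 0.05, and bars for list medians. Light harvesting genes have medians of -1.03 and -0.80.

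The second comparison asks which genes depend on JMJ705, as far as the label holds. In the libraries labelled jmj705, LHY, GAPA and RCA fell and GI rose, as they did in wox11, and LHY fell by less. LHY fell from 135 ± 17 to 47.5 ± 9.30 FPKM (log2 change -1.49, SE 0.16, adjusted p = 0.0187) and GI rose from 50.2 ± 8.95 to 144 ± 5.13 (log2 change 1.51, SE 0.15, adjusted p = 0.014). GAPA fell from 88.1 ± 9.34 to 37.8 ± 2.05 FPKM (log2 change -1.19, SE 0.12, adjusted p = 0.0145). RCA fell from 26.5 ± 2.09 to 14.2 ± 0.122 (log2 change -0.85, SE 0.12, adjusted p = 0.0487), a call at the edge of the threshold that ended under 9 of 11 other settings, with adjusted p between 0.0358 and 0.105, and without each single library (0.0853 to 0.258). Of the 10 clock genes, 1 rose, 1 fell and 8 did not pass, while 6 rose and 1 fell adjusted over the list alone. FKF1 stood at 14.3 ± 4.07 FPKM (adjusted p = 0.0847), and it passed without wild-type replicate 2 (adjusted p = 0.0176, range 0.0176 to 0.279). The clock list leaned up (median 0.63, camera adjusted p = 0.00284; adjusted p = 0.433 with an estimated correlation), and without jmj705 replicate 1 that adjusted p was 0.062 (range 1.67e-04 to 0.062). Its median was 0.32 without wild-type replicate 1 and 0.42 with a pseudocount of 5. The call of GI ended without wild-type replicate 1 (adjusted p = 0.0881), jmj705 replicate 1 (0.0862) or 2 (0.121) and with no FPKM filter (0.0719), and that of GAPA without the same 3 libraries (0.103, 0.0787 and 0.141). That of LHY ended without wild-type replicate 1 (0.124) or jmj705 replicate 2 (0.121), with no FPKM filter (0.105) and in a fit of 2 genotypes (0.0516). Over all alternatives the adjusted p ran from 0.0106 to 0.121 for GI, 0.0126 to 0.141 for GAPA and 0.0116 to 0.124 for LHY.

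The Calvin cycle, light harvesting, chlorophyll synthesis and chloroplast biogenesis lists fell in the libraries labelled jmj705 by camera, and each lost the call with an estimated correlation. In the Calvin cycle list (median -0.64, camera adjusted p = 9.42e-09; adjusted p = 0.112 with an estimated correlation), 2 of 13 genes fell over all genes and 10 adjusted over the list alone. Beside GAPA and RCA, cpFBP, a fructose-bisphosphatase gene, stood at 4.93 ± 0.134 FPKM in wild type and 2.03 ± 0.125 in these libraries (adjusted p = 0.0555), and it passed without the trend (adjusted p = 0.0443, range 0.0443 to 0.253). For light harvesting and photosystem genes (median -0.80, camera adjusted p = 1.97e-17; adjusted p = 0.433 with an estimated correlation), 26 of 26 values were negative, 0 passed over all genes by limma, 22 were lower at an unadjusted p under 0.05 and 22 fell adjusted over the list alone. LHCB3 stood at 119 ± 1.56 FPKM (adjusted p = 0.0655), PSBS1, a photoprotection gene, at 7.09 ± 0.134 in wild type and 3.53 ± 0.117 (adjusted p = 0.076), and LHCB6 at 105 ± 21.1 and 46.3 ± 12.1 (adjusted p = 0.137). For chlorophyll synthesis (median -0.49, camera adjusted p = 2.25e-07; adjusted p = 0.112 with an estimated correlation), 0 of 14 passed over all genes, 8 were lower at an unadjusted p under 0.05 and 8 fell adjusted over the list alone. CRD1 stood at 89.9 ± 0.514 FPKM in wild type and 53.0 ± 3.05, GUN4 at 34.2 ± 2.25 and 21.8 ± 0.385, and CHLH, a magnesium chelatase subunit gene, at 32.9 ± 2.00 and 17 ± 4.96. For chloroplast biogenesis (median -0.17, camera adjusted p = 0.0117; adjusted p = 0.433 with an estimated correlation), 0 of 12 passed over all genes, 2 were lower at an unadjusted p under 0.05 and 1 fell adjusted over the list alone. This was cpSRP43, at 16.7 ± 2.92 and 8.03 ± 0.755 FPKM (adjusted p = 0.0494 at a filter of 5 FPKM, range 0.0494 to 0.283), followed by SIG1 at 7.26 ± 0.0249 and 4.13 ± 1.20 and ST1 at 124 ± 12.4 and 96.3 ± 19.3. Without jmj705 replicate 2 this last list had a camera adjusted p of 0.16 (range 0.00309 to 0.16).

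Jasmonate and defence genes leaned up in the libraries labelled jmj705 (median 1.09, camera adjusted p = 0.00108; adjusted p = 0.596 with an estimated correlation), with 0 of 12 past the test, 2 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone. That gene was PR1a, a pathogenesis-related gene, at 0.561 ± 0.406 FPKM in wild type and 3.22 ± 0.696 (adjusted p = 0.0777). WRKY45 stood at 11 ± 9.0 FPKM and WRKY53 at 38.4 ± 29.6, with 17.3 and 59.4 FPKM in replicate 1 and 4.59 and 17.5 in replicate 2. Without jmj705 replicate 1 the list median was -0.0057 (adjusted p = 0.271), and without wild-type replicate 1 it was 0.10 (adjusted p = 0.0572), in a range of 1.51e-07 to 0.271. The median was 2.04 without wild-type replicate 2, 2.32 without jmj705 replicate 2 and 0.64 with a pseudocount of 5. The camera adjusted p was 0.0616 for heat shock genes, 0.118 for YABBY genes, 0.161 for floral MADS-box genes, 0.161 for vascular markers, 0.232 for meristem genes, 0.346 for auxin genes and 0.346 for cytokinin genes. It was 0.592 for cell division, 0.899 for Polycomb and demethylase genes, and 0.966 for gibberellin, hypoxia and root marker genes. Medians and tests differed in sign for the auxin, cytokinin, Polycomb, gibberellin and root marker lists, with medians of -0.04, -0.02, -0.03, -0.02 and 0.02. Heat shock genes (median -0.94) passed in a fit of 2 genotypes (camera adjusted p = 0.0423) and with a replicate block (0.0144), in a range of 0.0144 to 0.904 with all libraries. Their median was -0.51 with a pseudocount of 5, -0.53 at a filter of 5 FPKM, and -0.16 and -1.46 without wild-type replicate 1 or 2. Without jmj705 replicate 2 the floral MADS-box list passed (0.0156, range 0.0156 to 0.846), as did the meristem list (0.0457, range 0.0457 to 0.962). Adjusted over the list alone, 2 auxin genes (IAA13 and IAA9) and 1 Polycomb or demethylase gene (JMJ705) rose and 1 floral gene (MADS58) fell, against 0 of each list over all genes. At an unadjusted p under 0.05, 3 auxin genes, 2 cytokinin genes and 1 Polycomb gene were higher. By the same measure 3 heat shock genes, 2 meristem genes and 1 gene each of the floral, cytokinin and hypoxia lists were lower, and 0 genes of the cell division, gibberellin, root, vascular and YABBY lists were higher or lower. In the auxin list IAA13 stood at 26.5 ± 2.49 FPKM in wild type and 56.0 ± 9.45 in these libraries (adjusted p = 0.0501).

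Over all tested loci 86 passed in the libraries labelled jmj705, 69 higher and 17 lower, again most of them outside the gene lists. That count was 24 without wild-type replicate 1, 18 and 11 without jmj705 replicate 1 or 2, and 55 with quantile normalization.

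Tested directly against each other, the mutants differed at 61 loci, 37 higher and 24 lower in the libraries labelled jmj705 than in wox11. LHY was higher there (log2 difference 2.99, SE 0.16, adjusted p = 6.27e-04), LUX lower (log2 difference -3.04, SE 0.37, adjusted p = 0.0306) and PORA higher (log2 difference 1.5, SE 0.20, adjusted p = 0.042). GI, GAPA and RCA had log2 differences of -0.51, -0.09 and 0.35 with adjusted p of 0.448, 0.906 and 0.57. LHY kept this call under each alternative (adjusted p 4.57e-04 to 0.0321). LUX lost it without either library of wox11 or jmj705 (adjusted p 0.156 to 0.284) and PORA likewise (0.134 to 0.404). Both also lost it with a pseudocount of 0.1, no FPKM filter or quantile normalization (0.0501 to 0.203 for LUX and 0.0544 to 0.192 for PORA), in ranges of 0.00261 to 0.284 and 0.0311 to 0.404. The auxin, light harvesting and Calvin cycle lists differed by camera and lost the call with an estimated correlation. Auxin genes were higher in the libraries labelled jmj705 (median 0.24, adjusted p = 0.00155; adjusted p = 0.605 with an estimated correlation), with 3 higher adjusted over the list alone and 0 over all genes, and that list passed under each alternative (2.02e-04 to 0.0444). So were light harvesting genes (median 0.19, adjusted p = 0.0268; adjusted p = 0.947 with an estimated correlation), of which 1 was lower and 0 higher adjusted over the list alone, and Calvin cycle genes were lower (median -0.11, adjusted p = 0.0268; adjusted p = 0.781 with an estimated correlation), 3 of them adjusted over the list alone. At an unadjusted p under 0.05, 5 auxin genes, 4 light harvesting genes and 1 Calvin cycle gene were higher and 0, 2 and 3 lower. The light harvesting median turned to -0.033 without wox11 replicate 2 (adjusted p = 0.602), and its call ended without jmj705 replicate 1 (0.515), with no FPKM filter (0.0516) and with quantile normalization (0.133), in a range of 8.36e-13 to 0.602. That median was 0.48 without wox11 replicate 1 and 0.35 without jmj705 replicate 2. The Calvin cycle call ended without wox11 replicate 1 (0.0859), jmj705 replicate 1 (0.0733) or 2 (0.0714), in a range of 0.0132 to 0.0859. Jasmonate and defence genes were higher without wox11 replicate 1 (0.0441) or jmj705 replicate 2 (8.52e-06), in a range of 8.52e-06 to 0.66, and root markers without wox11 replicate 1 (0.0117), in a range of 0.0117 to 0.723. The count was 14 and 11 without wox11 replicate 1 or 2, and 23 and 19 without jmj705 replicate 1 or 2.

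In both mutants 34 loci differed from wild type in the same direction by limma, 26 up and 8 down, and 0 in opposite directions. With a replicate block they were 44, 21 up and 23 down. The mutations, a harvest time and a wild-type batch cannot be told apart as the source of shared changes. At an unadjusted p under 0.05 in both, 19 loci went opposite ways and 1099 the same way. Simulations with no effect but the shared wild-type libraries gave 5.43 and 243 on average. Named genes among the 34 loci were GI, up, and LHY, GAPA and RCA, down. The files pair no names with the rest. Loci were ranked by the smaller of their changes, among single-gene loci with their own coordinates and at least 5 FPKM in the higher genotype. LOC_Os03g43100 led the rises, from 0.228 ± 0.0702 FPKM in wild type to 40.2 ± 5.74 in wox11 and 12.0 ± 1.32 in the libraries labelled jmj705. LOC_Os05g50260 led the falls, from 26.6 ± 6.28 to 7.09 ± 1.12 and 7.44 ± 0.923. Independent lists of these sizes would share 0.315 loci up and 0.0649 down. With no effect but shared wild-type libraries, 100 simulations shared 0.120 loci on average and 2 at most. Across genes, which are not independent replicates, the fold changes of the mutants correlated at 0.613, against 0.499 in those simulations. Their covariance was 0.0774 against a simulated 0.0204, a difference of 0.0570. The simulations drew on limma's moderated variances. The variance of the wild-type mean measured from its 2 libraries was 0.0317, above that simulated covariance. The simulated values given here may therefore be too low, and the excess over them too large. With 2 wild-type libraries the controls cannot be split into sets of at least 2. With 1 wild-type library per mutant and none shared, the covariance was 0.0579 and, with the libraries exchanged, 0.0335. Part of the excess may therefore come from the shared controls. The count of 34 ran from 6 to 29 when 1 library was left out, with 9 without wild-type replicate 1, 12 and 14 without wox11 replicate 1 or 2, and 14 and 6 without jmj705 replicate 1 or 2.

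**Figure D3:**
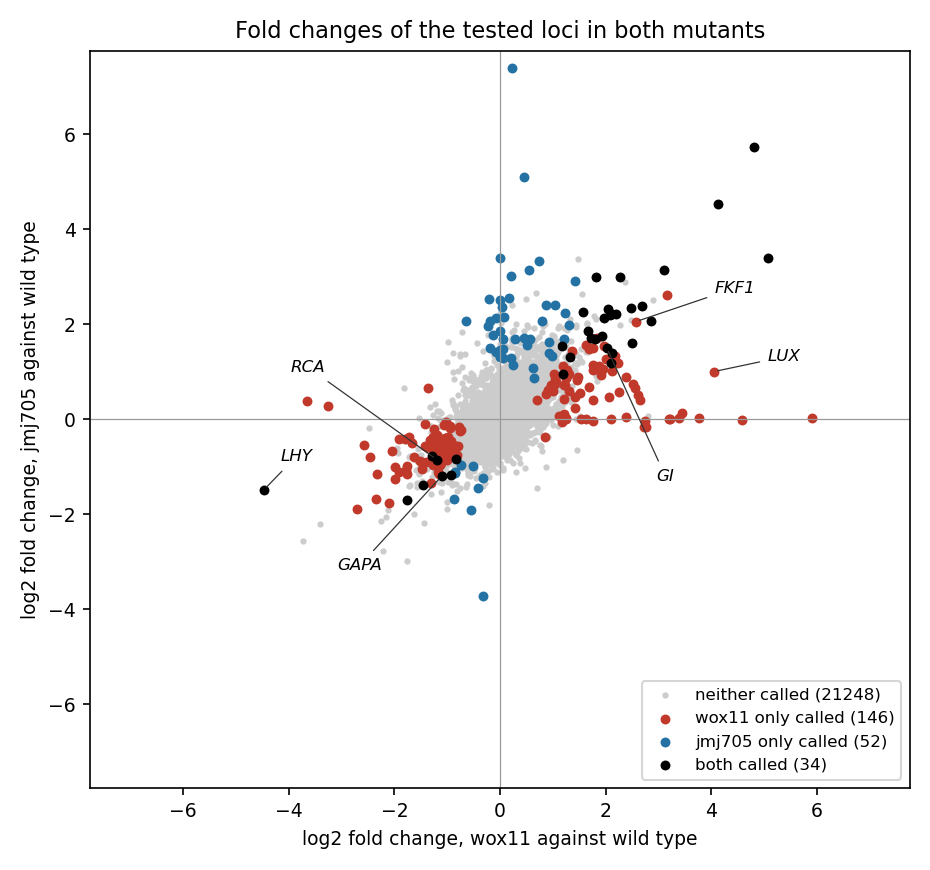
Log2 fold change (FPKM + 1) against wild type in wox11 (horizontal) and in the libraries labelled jmj705 (vertical) for 21480 loci, with colours for loci called at adjusted p under 0.05 in one mutant, the other or both. The 34 loci called in both lie at the upper right and lower left.

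Anti-FLAG ChIP-seq asks where over-expressed JMJ705 lies on chromatin and whether that changes without WOX11. Each background has 1 peak list, called against its own control, so no difference between them has a replicate check. The wild-type background list held 1551 peaks with a median length of 950 bp from 4488720 tags after removal of duplicates, and the wox11 background list 1309 peaks with a median length of 937 bp from 6811451 tags. The authors' median fold enrichment was 6.65 and 6.57, and their median false discovery rate 1.65% and 6.09%. 1532 wild-type background peaks and 0 wox11 background peaks had a rate of 5% or less. Control tags kept numbered 15531116 and 11816531, so these rates come from unlike depths and are not compared between the lists. Of the wild-type background peaks, 436 (28.1%, 95% exact Clopper-Pearson interval 25.9 to 30.4%) overlapped a wox11 background peak by at least 1 bp, against 0.777% when peaks were placed at random within chromosomes. Of the wox11 background peaks, 438 (33.5%, interval 30.9 to 36.1%) overlapped in turn, against 0.913%. These intervals cover counting error alone. Random placement makes no allowance for regions where peaks gather for reasons other than JMJ705. Sharing above it is therefore not by itself evidence of JMJ705 binding. Of the 10 peaks with the highest fold, 10 in the wild-type and 8 in the wox11 background list were shared. The rates of those 10 peaks ran from 2.22 to 50% and from 18.5 to 100%. Shared peaks had a median fold of 9.75 in the wild-type background list and the rest 6.21, against 6.73 and 6.54 in the wox11 background list. Peaks lay within 1 kb of a gene locus in 67.0% and 67.2% of cases, and random places in 68.4% and 68.6%.

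Both backgrounds had a peak at WOX11 and at JMJ705 themselves. At WOX11 the peaks ran from 29072849 to 29073894 on chromosome 7 in the wild-type background (fold 8.22) and from 29072995 to 29074003 in the wox11 background (fold 8.95), across 1 end of the locus. At JMJ705 they ran from 39492859 to 39494579 on chromosome 1 (fold 7.38) and from 39492990 to 39494613 (fold 5.16), with another at 39497312 to 39500009 in the wild-type background list (fold 4.41). These apices over-express JMJ705, and tags of an added gene copy were not told apart from those of the native locus. The JMJ705 peaks therefore do not by themselves show binding there. RR2, a type-A response regulator of cytokinin signalling, had a shared peak starting at 21131141 on chromosome 2 in each list (fold 7.09 and 7.75). The demethylase gene JMJ703, the floral gene MADS6 and PETC, an electron transport gene, also had peaks in both lists. LHY, SD1, DL, MADS5, CRL5 and YAB3 had a peak in the wild-type background list alone, with folds of 4.18, 5.32, 8.10, 8.80, 7.54 and 8.61. Within 1 kb, LUX, cpTPI, SIG1, JMJ706, PRR37, PRR95, CHLH, DVR and TKT had one in the wox11 background list alone, with folds of 10.6, 15.5, 11.3, 12.6, 9.86, 7.10, 5.89, 8.47 and 7.82. A peak listed in 1 background may lie under the threshold in the other, where tags differ in number, so these lists show no loss or gain of binding.

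**Figure D4:**
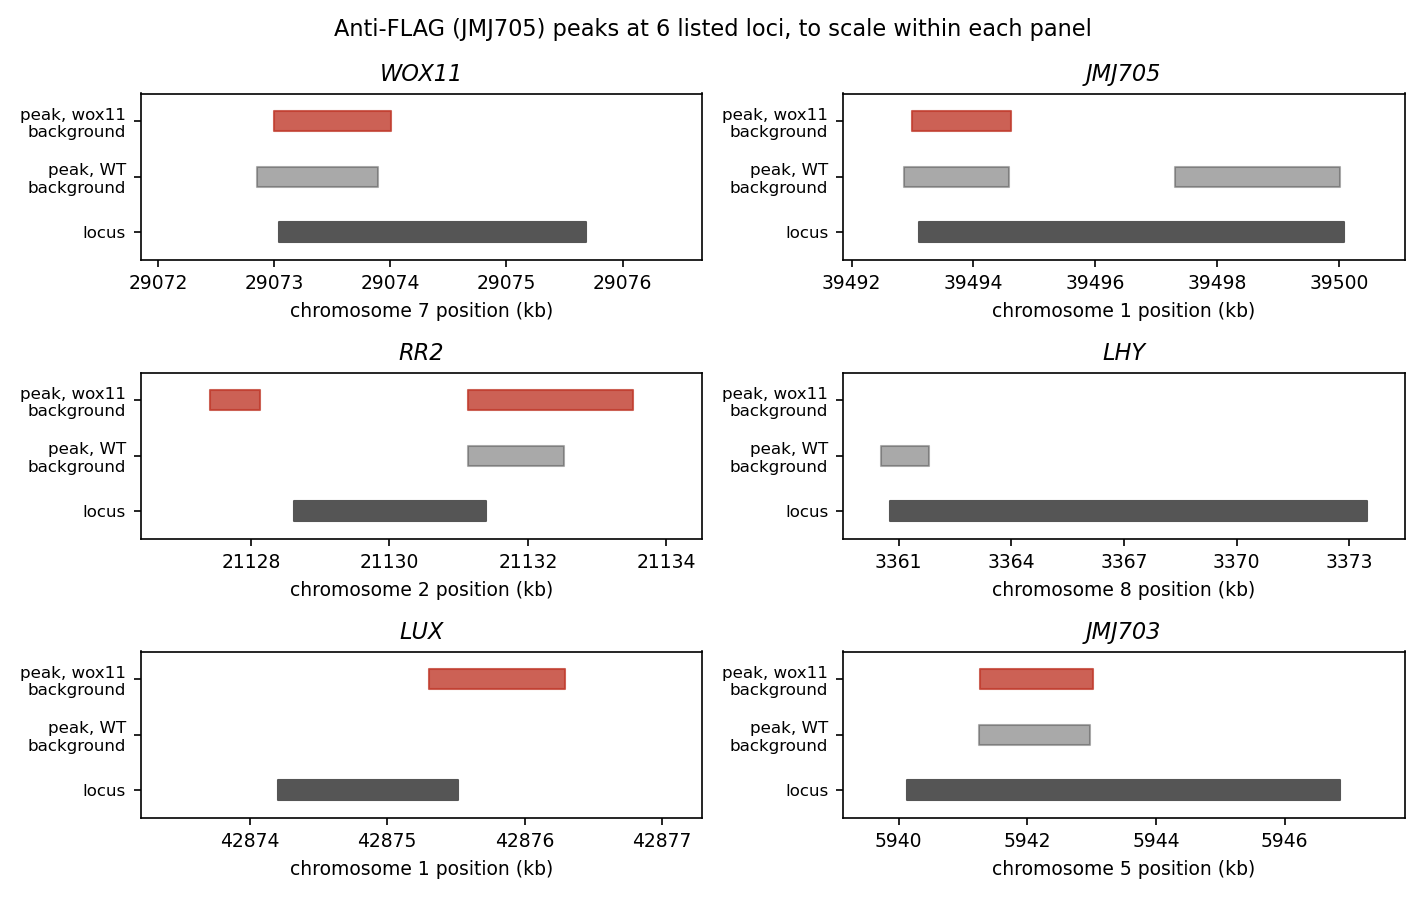
Anti-FLAG peaks of over-expressed JMJ705 in the wild-type background (light grey) and wox11 background (red) at 6 loci (dark grey), against position in kb along the chromosome, to scale within each panel. WOX11, JMJ705, RR2 and JMJ703 carry overlapping peaks in both lists, LHY in the wild-type and LUX in the wox11 background list.

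The last comparison joins the assays and asks whether genes near a JMJ705 peak changed in the mutants. Of 17439 tested loci with their own coordinates, 476 lay within 1 kb of a wild-type background peak. In wox11, 4 of them rose and 3 fell, or 1.47% against 0.819% of other loci (two-sided Fisher's exact test, p = 0.123, adjusted p = 0.307 over 10 tests). LHY was among the falls. In the libraries labelled jmj705, 4 rose and 2 fell, or 1.26% against 0.401% (p = 0.0156, adjusted p = 0.0853 by the same exact test). Near wox11 background peaks lay 402 tested loci, of which 3 rose, LUX among them, and 0 fell in wox11 by limma (adjusted p = 1 by the exact test). At an unadjusted p under 0.05, 22 of these loci were higher and 34 lower in wox11. In the libraries labelled jmj705, 44 were higher and 22 lower by that measure. Over the sets of peak genes, median log2 changes lay between -0.04 and 0.00 in both mutants, with camera p between 0.447 and 0.92. RR2 and JMJ703, with peaks in both lists, had log2 changes of 0.24 and 0.06 in wox11 and 0.13 and -0.02 in the libraries labelled jmj705. With all libraries and 1 kb on each side of a locus, used because the files give no strand, no set of peak genes passed a test after adjustment. For jmj705 and wild-type background peaks the exact test passed with peaks over the gene body alone (1.20 percentage points above other loci, adjusted p = 0.0327) and without jmj705 replicate 1 (0.561 points, adjusted p = 0.0429), while without wild-type replicate 1 or 2 the difference was 0.0940 and 0.0990 points and without jmj705 replicate 2 0.166, in a range of adjusted p of 0.0309 to 1.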

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

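The tests of explanations and the inclusion of loci without a gene name were chosen after the result was seen, and the test between the mutants was planned. The mutants differed from each other at 61 loci by the test of the difference itself. Among named genes these were LHY (log2 difference, jmj705 minus wox11, 2.99, SE 0.16, adjusted p = 6.27e-04), LUX (-3.04, SE 0.37, adjusted p = 0.0306) and PORA (1.5, SE 0.20, adjusted p = 0.042). With 1 library of wox11 or jmj705 left out the adjusted p was 0.156 to 0.284 for LUX and 0.134 to 0.404 for PORA. Outside the loci used in the comparisons, 13 loci without a gene name were called in wox11 and 14 in the libraries labelled jmj705 when the 909 such loci above the filter were included, all of them higher than in wild type.

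The pattern of clock and photosynthesis genes in both mutants has a candidate explanation in the time of harvest, and evening clock genes (GI, LUX, FKF1, PRR1 and ELF3) had a sign opposite to that of LHY in 9 of 10 gene and mutant pairs, of which 4 passed limma's test, a tally of genes that belong to the pattern itself and so no evidence for this explanation. The labels give no time of day and both libraries of a genotype could share one, so harvest time and genotype cannot be told apart. A smaller share of green tissue in the wox11 apices could not be decided. Light harvesting genes had a median log2 change of -1.03 and Calvin cycle genes -0.08 (mean -0.35, SD over members 0.50). The difference was 0.95 (permutation test of list membership, two-sided p = 2.60e-04). That test takes genes as independent, while light harvesting genes had an estimated correlation of 0.80, so it measures no spread between samples. RCA, GAPA, SBP, RBCS2 and cpFBA fell adjusted over the list alone (-1.20 to -0.63), while GAPB, PRK and RBCS3 had 0.23, -0.23 and 0.03. Expression outside green tissue was not tested, so less green tissue stays open in wox11. In the libraries labelled jmj705 the difference was 0.16 (permutation p = 0.208), so less green tissue stays open there, as does an effect of genotype, which was not tested apart from harvest.

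The likeness of the mutants' fold changes is argued not to come wholly from chance values of the shared wild-type libraries. When wox11 was set against 1 wild-type library and jmj705 against the other, the covariance was 0.0579 and, with the libraries exchanged, 0.0335, against 0.0774 with both shared. Wild-type plants that differed as a batch from both mutants stay a possible explanation. The mutants differed from each other at 61 loci, fewer than the 180 and 86 against wild type, and a batch, a harvest time and a shared effect of the mutations all give this.

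JMJ705 was higher in the libraries labelled jmj705 than in wild type, with a ratio of means of 1.86. An exchange of the jmj705 and wox11 labels is argued against by WOX11, which was 1.59 log2 units higher in the libraries labelled jmj705 than in those labelled wox11 (SE 0.23, adjusted p = 0.0602 over all loci, limma). Its FPKM was 4.57 and 7.56 in the former and 1.49 and 1.11 in the latter. An exchange with wild type could not be decided, because JMJ705 differed by 0.20 between wox11 and wild type (SE 0.13, adjusted p = 0.688, limma). A mutant allele that still makes, or makes more of, an altered transcript was not tested, since the files give 1 value per locus.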

How the results depend on the processing

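Alternatives were fixed before the data were examined, except the inclusion of unnamed loci, the fit without the trend, the removal of merged loci and the count for both mutants in fits of 2 genotypes, which were chosen after seeing the data. With a library left out, 3 medians of lists that had a call changed sign, and the cause was not tested. Of 37 medians of lists with no call, 22 changed sign in at least 1 such fit. The jasmonate and defence median ran from -0.13 (without wild-type replicate 1) to 1.42 in wox11 and from -0.0057 (without its replicate 1) to 2.32 in jmj705, and the light harvesting median between the mutants from -0.033 (without wox11 replicate 2) to 0.48. With no FPKM filter (32888 loci tested) the count for wox11 was 34 and that for both mutants 8. With quantile normalization jmj705 had 55 and both mutants 22. With a pseudocount of 5 both mutants had 21, and in fits of 2 genotypes 20. The cause was not tested. When each library was left out in turn, which leaves fewer libraries and assumes that a lone library varies like the other groups, counts ran from 21 to 182 for wox11, 11 to 86 for jmj705, 11 to 64 for their difference and 6 to 29 for both, and the correlation of fold changes from 0.512 to 0.731. The simulations with no effect held all 6 libraries, and the correlation they give depends on how many libraries each genotype has. Correlations with 1 library left out therefore have no simulated value to be set against. Under every other alternative the correlation was 0.589 to 0.625.

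Replicate numbers are shared by the genotypes, but no label says what they mark, so they were taken to be shared in number only. Differences between replicates 1 and 2 correlated at 0.292, 0.118 and 0.114 between genotypes, all above 0.1, which 1 of the 4 ways of numbering these libraries gives. This is a hint of a shared replicate effect, for which counts without the block make no allowance. With the replicate block the counts were 230 for wox11 (96 up, 134 down), 89 for jmj705 (60 up, 29 down), 69 for their difference and 44 for both (21 up, 23 down, against 26 and 8 without it). RCA in jmj705, PORA between the mutants and the jasmonate list in wox11 lost their calls under the block, while LHCB6, PR1a and the heat shock list in jmj705 gained one, and it changed no other call of a named gene or list.

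For single genes called with all libraries and settings as planned, 170 values under alternatives with all libraries kept the call and 39 lost it, and with 1 library left out 59 kept and 55 lost it. For called lists the numbers were 176 and 11 with all libraries, and 87 and 12 with 1 left out, beside the 3 that changed sign. Of genes and lists not called, 6 and 4 values with all libraries became calls, and 4 and 13 with 1 left out. In the better-scoring 776 and 655 peaks of the lists, 32.5% and 38.9% of peaks were shared, and 63.7% of wild-type background peaks lay within 1 kb of a gene. For the median log2 change of genes near any wild-type or any wox11 background peak, none of the 44 alternatives passed (smallest p = 0.102, from random gene sets matched on expression, a permutation test). For the share of called genes, 3 of 40 alternatives passed Fisher's exact test, all for jmj705 near wild-type background peaks, where the share lay 0.860 percentage points above that of other loci. It lay 1.20 points above it with the gene body alone (adjusted p = 0.0327), 1.04 with the replicate block (0.0309) and 0.0940 (without wild-type replicate 1) to 0.612 (without wox11 replicate 2) with 1 library left out, passing without jmj705 replicate 1 (0.0429), and the cause was not tested. For genes near wild-type background peaks alone, not run under the alternatives, the permutation test with random gene sets gave p = 0.0539 in wox11. With 1 list per background, what the lists share could not be told from their depth. The expression calls rest on 2 libraries per genotype. Counts with 1 library left out mix the loss of a library with libraries that stood apart, and the 2 were not separated.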

Other observations

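The list test of phytoalexin genes without the FPKM filter was chosen after the result was seen, and the other values of this part carry no test. Genes that make momilactone, a diterpenoid phytoalexin of rice, stood higher in both mutants at very low levels. They lie in a cluster on chromosome 4, and 8 of the 9 phytoalexin genes listed were under the FPKM filter, so the list was tested without the filter. MAS, a momilactone synthase gene, stood at 0.125 FPKM in wild type, 0.971 in wox11 and 1.31 in the libraries labelled jmj705. CYP99A3 stood at 0.112, 0.626 and 0.696 FPKM, CYP99A2 at 0.152, 0.540 and 0.696, KSL4 at 0.101, 0.601 and 0.529, and CPS4 at 0.119, 0.516 and 0.636. In each of these 5 genes and in KSL7 all 4 mutant libraries lay above both wild-type libraries. No gene passed limma's test singly, 6 and 4 were higher at an unadjusted p under 0.05, 3 rose in wox11 and 4 in the libraries labelled jmj705 adjusted over the list alone, and camera gave adjusted p = 2.51e-04 and 2.13e-04. With an estimated correlation these became adjusted p = 0.234 and 0.286.

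Many loci that rose were near 0 in wild type. Of the 26 loci up in both mutants, 12 were below 1 FPKM in both wild-type libraries and all 12 of these were above 1 FPKM in all 4 mutant libraries. A locus this low in wild type can pass the filter and be called up mainly when the mutant libraries exceed 1 FPKM. That all 12 did so was therefore largely set in advance. Of all loci up in wox11, 35 of 98 were below 1 FPKM in both wild-type libraries, and of those up in the libraries labelled jmj705, 37 of 69. The share of all tested loci that were this low in wild type was not set beside these counts.

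Libraries of the same genotype stood apart at stress genes. The median deviation of jasmonate and defence genes from their 6-library mean was -1.45 log2 in wild-type replicate 1 and 0.09 in replicate 2, and 1.66 and -0.17 in jmj705 replicates 1 and 2. For heat shock genes it was 1.22 in wild-type replicate 1 and -0.08 in replicate 2. Light harvesting genes deviated by -0.12 in wox11 replicate 1 and -0.66 in replicate 2.

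The shared peaks with the highest scores carried high false discovery rates in the authors' lists. The top shared peak of the wild-type background list, on chromosome 9 from 2309795 to 2312018, had a fold of 23.4 and a rate of 100%. The top one of the wox11 background list, on chromosome 11 from 12351670 to 12353256, had a fold of 22.5 and a rate of 100%. The top peaks of a single list had rates of 4.76% in the wild-type and 50% in the wox11 background. In all, 9 and 84 peaks had a rate above 10%.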
